A study of Mus musculus with 41 samples.

How the data were processed

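Expression was measured in 41 single neurons of mouse binocular visual cortex, 23 sorted as callosal projecting neurons (CPN) and 18 as callosal receiving neurons (CRN). Per the labels' protocols, neurons were sorted into the buffer of the kit and full-length cDNA libraries were made from each neuron with a SMART-Seq single-cell kit, which adds no unique molecular identifiers, so PCR copies of a molecule count as separate reads. The submitters' processing notes name the aligner STAR 2.7.10 and the genome builds GRCm38 and mm10, which are names of the same mouse assembly. The program that counted reads, its annotation, its use of strand and its treatment of reads shared between genes are not given in the sources used here, so values of near-identical family members and of overlapping genes are uncertain.

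The deposited values are read counts: whole numbers per gene and cell, not normalized, for 15206 genes in 41 cells, with entries for the reporters GFP and mCherry among them. Every gene of the table has a read in at least 1 cell. Transcripts of the mitochondrial genome were not analysed here, since 0 of the genes carry their names. Groups were taken from the sorted cell label of each sample, and which reporter marks which group was read from the counts, since the labels used here do not say it. Of the gene symbols, 14599 matched GENCODE release 21 for mouse (M21, on GRCm38), from which coordinates were taken.

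Counts were divided by the total of each cell or group and expressed per 1000000 reads (CPM). The main level of a group was the sum of its cells' counts over the sum of their totals, which gives deeper libraries more weight, and the difference was the log2 ratio of CPN over CRN. A group with fewer than 3 reads of a gene was set to a floor of 3 counts over the group for the ratio, where the rule fixed at the start named groups with 0 reads only; list medians include such genes at that bound, and no fold is given for a gene with 1 to 3 reads. The mean of per-cell CPM, with cells weighted equally, stood beside it. Because each sample is 1 cell and no animal is named, each group is 1 sample: no p-value, standard error or number of differing genes was computed. Poisson intervals for summed counts cover the counting of reads only. Clopper-Pearson intervals for shares of cells cover the sampling of cells as if independent, not that of animals. Both are at 95%. Total reads per cell ran from 476523 to 76517039, so 1 read is worth far more CPM in the shallowest cell than in the deepest, and detection of low genes depends on depth.

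Before the data were examined, 26 gene lists and the rule for named genes were fixed. A list member counted as measured at a mean of at least 1 CPM over all cells (12298 genes reach it), and a median was given for the 22 lists with at least 3 measured members. Its percentile was taken among 10000 random lists of the same size, drawn from 20 bins of mean expression, as a description of these libraries only; medians below percentile 2.5 or above 97.5 are called outside the middle 95%. Named genes had a mean of at least 10 CPM and a ratio of at least 2 in the same direction in the pooled level, in the equal-weight mean and with each cell left out in turn; of these, the 12 with the largest difference in the share of cells detected in each direction were named, leaving out predicted genes, pseudogenes, and X-inactivation and Y-linked genes. Up to 2 members of each list in each direction with a mean of at least 10 CPM, and markers fixed at the start, among them Slc17a7, Gad1, Gad2, Cux2, Rorb, Fezf2 and Foxp2, were named whatever their values. Genes named outside this rule, in the closing observations, were chosen after their values were seen.

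The cells were checked for repeated libraries: 0 columns were identical, and log-scale correlations across genes over the 820 pairs of cells ran from 0.503 to 0.764 (median 0.640). The calculation was tested on simulated data, with counts drawn for the 12298 genes from the mean and spread of each gene over all 41 cells and the read total of each cell, and 200 genes altered by known folds in the 23 CPN cells but not in the 18 CRN cells. Median log2 ratios were 1.17 and -1.01 for true values of 1 and -1, and 1.68 and -2.01 for 2 and -2. Unaltered genes had an SD of 1.30 in the pooled log2 ratio, a rough guide to how far single genes scatter with this number of cells. The spread given to a gene was capped, so scatter is understated for the most variable genes, such as those read in few cells. That spread also includes any difference between the groups. Of 100 unaltered lists, 8 were outside the middle 95%, and in a separate draw of Poisson counts the intervals covered 96.2% of the true values. Genes were drawn independently of each other within a simulated cell, and members of random lists were drawn separately. Neither therefore shows how far the median of a list of genes that vary together from cell to cell scatters.

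Alternatives were equal weighting of cells, totals without the 10 most abundant genes, TMM (edgeR 4.0.16) and median-of-ratios factors, differences of mean log2(CPM + 1), stricter and looser filters on list members, each class of library names alone, each cell left out in turn, detection at 10 CPM or more, and detection in reads thinned to 1000000 per cell, which leaves out 1 cell. Added after seeing the data were removal of the deepest library of each group, thinned list medians, TMM and median-of-ratios factors for lists, and pseudocounts of 0.1 and 10 for lists. TMM, median-of-ratios, totals without the 10 most abundant genes and equal weighting moved the median of all genes by less than 0.1 on the log2 scale. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3.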

Results

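Single neurons of the mouse binocular visual cortex, the part of visual cortex that serves the field seen by both eyes, were labelled with viral reporters, isolated by fluorescence-activated sorting and sequenced one by one. Each of the 41 libraries was 1 neuron of a wild-type mouse. Of these, 23 were callosal projecting neurons (CPN), which send an axon through the corpus callosum to the other hemisphere, and 18 were callosal receiving neurons (CRN), which receive such input. Tissue was handled in actinomycin D (5 µg/ml), an inhibitor of transcription that limits expression induced by dissociation. The labels named no animal, so each group counted as 1 sample, there was no replicate check, and no test between groups was possible. Levels are counts per 1000000 reads (CPM) summed over the cells of a group, with exact Poisson intervals, and shares of cells with at least 1 read carry exact Clopper-Pearson intervals, both at 95%. The Poisson intervals cover the counting of reads only, and reads without molecular identifiers are not independent molecules. The Clopper-Pearson intervals cover the sampling of cells as if independent, and cells of 1 animal are not independent animals. SDs describe the spread over cells.

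Read depth differed widely between cells. Total reads per cell ran from 2796995 to 76517039 in CPN (median 11556514) and from 476523 to 58146183 in CRN (median 11698209.5). Between 5640 and 10042 genes had a read in a CPN cell (median 7616), and between 6264 and 10127 in a CRN cell (median 8483). CPN cell 23 held 20.0% of the 382737064 CPN reads and CRN cell 10 held 25.5% of the 227956041 CRN reads. Some library names ended in a suffix that the labels do not explain: 10 CPN and 10 CRN cells carried it, and 13 CPN and 8 CRN cells did not. Cells with the suffix had higher Malat1, a nuclear long non-coding RNA (mean 21280 CPM ± 17710, SD, n = 10, against 3588 ± 2406, n = 13, in CPN; 33340 ± 21560, n = 10, against 7707 ± 7377, n = 8, in CRN). Rorb, a layer marker fixed at the start, had a lower median in cells with the suffix in both groups. In CPN the median was 3.57 CPM with the suffix (n = 10) and 235 CPM without it (n = 13). In CRN it was 2.64 CPM (n = 10) and 398 CPM (n = 8). The suffix was treated as a possible batch, but the classes may also differ in the kinds of cell they hold, which was not tested. Values within each class of library names are given where they turn the direction of a printed level or differ much from the pooled ratio.

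The reporters separated the groups completely. GFP exceeded mCherry in 23 of 23 CPN cells, at 58.6 to 2358 CPM (median 545), and mCherry exceeded GFP in 18 of 18 CRN cells, at 625 to 5557 CPM (median 2115). The reporter of a cell's own group was at least 10.5 times the other one in CPN and at least 34.2 times in CRN. Reads of the other reporter occurred in 16 CPN cells, reaching 63.4 CPM, and in 11 CRN cells, reaching 31.4 CPM.

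**Figure D1:**
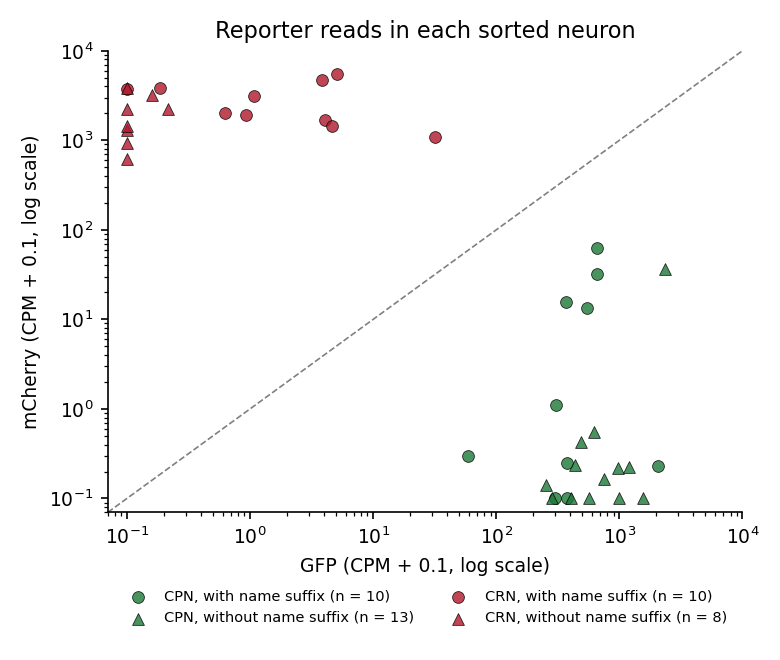
GFP (horizontal axis) and mCherry (vertical axis) in each of the 41 neurons, in CPM plus 0.1 on log scales, coloured by sorted group, with circles for library names with the suffix and triangles for those without. The dashed line marks equal levels; the 23 CPN cells lie below it and the 18 CRN cells above it.

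Both groups consisted of excitatory neurons by their marker genes. Slc17a7, the vesicular glutamate transporter of cortical excitatory neurons, had reads in 41 of 41 cells, from 74.9 to 1150 CPM, and its pooled level was 537 CPM in CPN and 576 CPM in CRN. Its log2 ratio was -0.10, or 0.50 without CRN cell 10, and -0.25 and 0.36 in cells with and without the suffix. Gad1 and Gad2, the enzymes of GABA synthesis, had reads in 8 cells, never above 1.33 CPM together; 1 of 23 CPN and 1 of 18 CRN cells held Gad1 reads, and 2 and 4 cells held Gad2 reads.

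The comparison of CPN with CRN addressed whether neurons that send and neurons that receive callosal axons differ in the genes they express. CRN cells carried higher levels of interferon-induced genes: Isg15, a ubiquitin-like antiviral protein, had reads in 14 of 18 CRN cells and 3 of 23 CPN cells. Markers of layer 5 were also higher in CRN, and Fezf2, the transcription factor that specifies subcerebral projection neurons, had reads in 7 of 18 CRN cells and 0 of 23 CPN cells. CPN cells more often had reads of S100a6, a calcium-binding protein (21 of 23 against 3 of 18), and of Rspo1, a secreted activator of Wnt signalling (12 of 23 against 1 of 18). GABA receptor subunits and general glutamatergic genes were slightly higher in CPN as groups, but the former not beyond random lists with cells weighted equally and the latter not in cells without the suffix. The median log2 ratio of CPN over CRN over the 12298 measured genes was -0.12.

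Of the 12 genes named for CPN, S100a6 (chromosome 3, 90612882 to 90624181, GRCm38) showed the largest gap in detection, with a share of 91.3% of CPN cells (interval 72.0 to 98.9%) and 16.7% of CRN cells (3.58 to 41.4%). Its pooled level was 89.8 CPM (88.8 to 90.7) in CPN and 23.5 CPM (22.9 to 24.2) in CRN, a 3.82-fold difference that became 22.6-fold without CRN cell 9, and its log2 ratio was 0.99 in cells with the suffix and 3.85 in cells without it. Igfn1 had reads in 18 of 23 CPN and 4 of 18 CRN cells and was 3.12-fold higher in CPN, or 12.6-fold without CRN cell 4. Rspo1 (chromosome 4, 124986430 to 125009099) stood at 51.9 CPM (51.2 to 52.7) in CPN, and all 342 CRN reads came from CRN cell 1. Adcyap1, which encodes the neuropeptide PACAP, reached a mean of 196 CPM ± 478 (SD, n = 23) in CPN and 35.3 ± 75.9 (SD, n = 18) in CRN, with reads in 17 and 6 cells; its pooled log2 ratio of 2.11 was 2.81 without CRN cell 1. Cygb, a globin of the cytoplasm, was detected in 20 CPN and 8 CRN cells, and Dact2 in 23 and 11. The remaining genes of this set were Myh14, a non-muscle myosin heavy chain (16 and 3 cells), Rnd3 (13 and 2), Mthfsl (18 and 6), Nbl1, a secreted BMP antagonist (14 and 3), Lrrc14 (15 and 4) and Fxyd5 (13 and 3). Within the classes of library names, 11 of the 12 kept the higher level in CPN in both. Rnd3 was the exception, with a log2 ratio of 2.79 in all cells and -0.15 among cells with the suffix. Rspo1 had 1659 CPN and 0 CRN reads in cells with the suffix and 18216 and 342 in cells without it.

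Among the 12 genes named for CRN, 4 were interferon-induced members of the list fixed for that response: Isg15, Usp18, Oasl2 and Irf7. Isg15 (chromosome 4, 156199424 to 156200818) stood at 292 CPM (289.6 to 294) in CRN and 5.73 CPM (5.49 to 5.97) in CPN, and 2189 of the 2192 CPN reads came from CPN cell 6. Its log2 ratio was -5.67 in all cells and -5.48 in cells with the suffix, and in cells without it there were 7926 CRN reads and 1 CPN read. Without CRN cell 10 its ratio was 29.3-fold. Irf7, a transcription factor that amplifies interferon signalling, had reads in 9 of 18 CRN cells (50%, interval 26.0 to 74.0%) and 0 of 23 CPN cells, which allows a share of up to 14.8%. Its level in CRN was 60.1 CPM, with 11415 of 13699 reads in CRN cell 10 and 82 in cells without the suffix. Usp18, a protease that removes Isg15 from its targets, had 11118 reads over 10 CRN cells and 2 reads in 1 CPN cell. Oasl2 had reads in 10 CRN cells and in CPN cell 6 alone. Lgals3bp, a secreted glycoprotein, had 17715 reads over 11 CRN cells and 1 read in CPN.

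Among the other genes named for CRN, Phgdh, which catalyses the first step of serine synthesis, had 6846 reads over 10 of 18 CRN cells (30.0 CPM) and 1 read in CPN. Mthfd2, a mitochondrial folate enzyme, had reads in 13 of 18 CRN and 4 of 23 CPN cells and was 13.5-fold higher in CRN, or 78.0-fold without CPN cell 8, with log2 ratios of -6.15 in cells with the suffix and -1.10 in cells without it. The other named genes were Mtfr1 (9 of 18 CRN and 0 of 23 CPN cells), Dleu7 (13 and 2), Atf6b (16 and 7), the non-coding RNA Snhg5 (13 and 4) and the p53-induced nuclease Aen (15 and 7). Within the classes of library names, 11 of the 12 were at least 2-fold higher in CRN in both; Aen had a log2 ratio of -4.45 in cells with the suffix and 0.02 in cells without it. These 24 genes were chosen by the gap in detection between these same cells, so the gaps are not unbiased estimates.

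**Figure D2:**
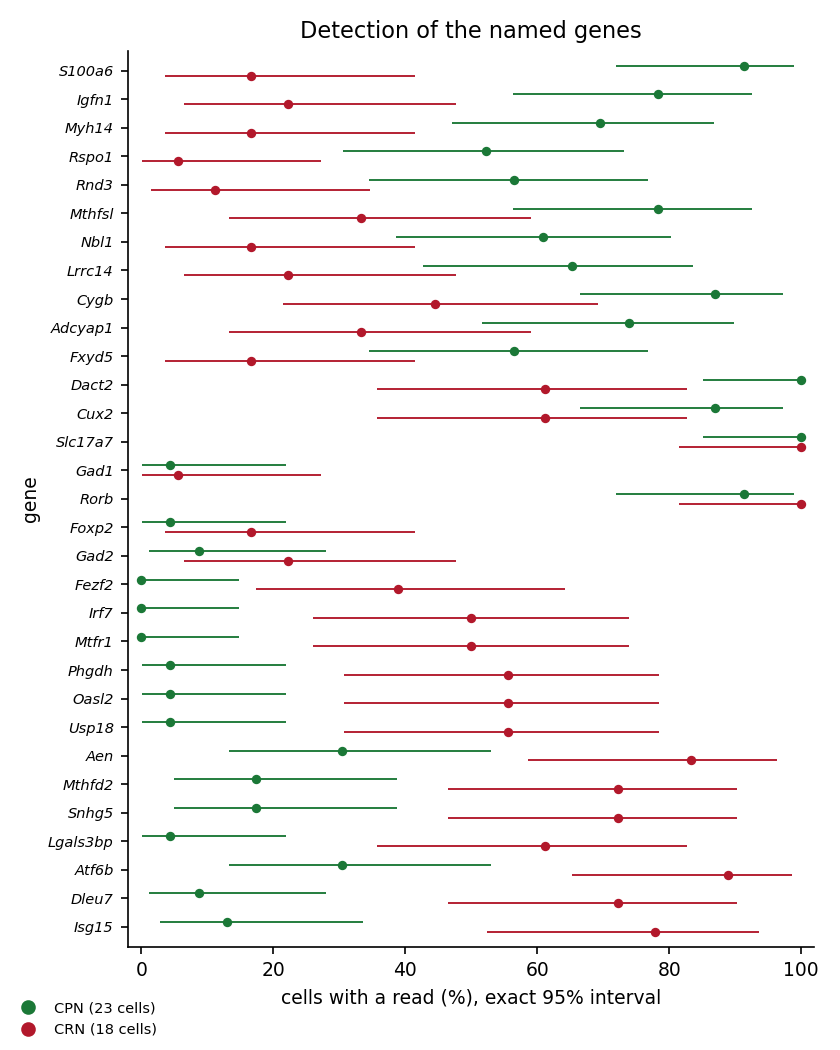
Share of cells with at least 1 read (horizontal axis, percent) for the named genes (vertical axis) in 23 CPN and 18 CRN cells; points are shares and lines exact 95% Clopper-Pearson intervals, which cover the sampling of cells only. S100a6 stands at 91.3% of CPN and 16.7% of CRN cells, and Isg15 at 13.0% and 77.8%.

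The interferon and antiviral list, fixed before the data were examined, was the list furthest from 0. Of its 17 measured members, 16 were higher in CRN, each by over 2-fold, and the median log2 ratio was -5.04, below all of 10000 random lists matched on expression, as a description of these libraries. Rsad2, which encodes the antiviral enzyme viperin, had 19506 reads over 5 CRN cells and 1 read in CPN, all in cells with the suffix. Ifi27 was the member that went the other way, at 19.3 CPM in CPN and 17.6 CPM in CRN, and it was higher in CRN when cells were weighted equally (log2 ratio -0.65) or without CPN cell 18 (-1.30), and in cells with the suffix (-2.17) but not in those without it (2.76). A CRN cell had reads of a median of 11.5 members (range 2 to 17) and a CPN cell of a median of 4 (range 2 to 14). The response was not uniform within CRN: the summed level of the members ran from 91.8 to 13930 CPM over CRN cells and from 85.4 to 1016 CPM over CPN cells. The median was -5.48 in cells with the suffix and -3.59 in cells without it, and -7.80 without CPN cell 6. Reads of the Ifit and H2 families can be shared between near-identical members, and how such reads were counted is not given in the sources used here.

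**Figure D3:**
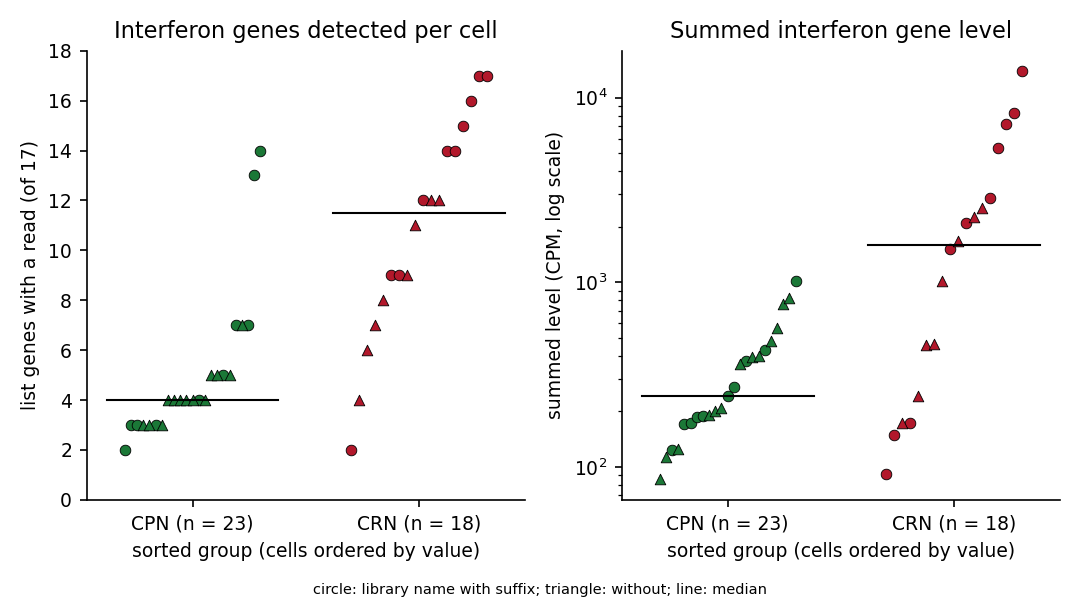
Number of the 17 measured interferon genes with a read (left) and their summed level in CPM on a log scale (right) in each of 23 CPN and 18 CRN cells; cells are ordered by value, circles have the library name suffix, triangles do not, and lines are medians. The median number was 4 in CPN and 11.5 in CRN, and the highest summed level was 1016 CPM in CPN and 13930 CPM in CRN.

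Deep-layer markers were higher in CRN. In the list for layer 5 intratelencephalic neurons, 6 of 7 measured members were higher in CRN, each over 2-fold, and the median log2 ratio was -3.26 (percentile 0.03 of random lists). Fezf2 (chromosome 14, 12342094 to 12348189) stood at 24.4 CPM (23.7 to 25.0) in CRN, in 38.9% of cells (interval 17.3 to 64.3%), and at 0 reads in CPN, which allows a share of up to 14.8%. Etv1, a transcription factor of layer 5, had reads in 8 CRN and 4 CPN cells (58.0 and 2.00 CPM), with a log2 ratio of -4.86 that was -6.64 without CPN cell 1 and -4.11 without CRN cell 12. Rorb went the other way (203 CPM in CRN and 284 CPM in CPN, in 18 and 21 cells), though only in cells with the suffix (log2 ratio 2.44, and -0.12 without it). Among cells with the suffix its median was 3.57 CPM in CPN and 2.64 CPM in CRN. In each group 4 of these 10 cells reached 10 CPM, so the ratio of 2.44 rests on few cells. The layer 5 extratelencephalic and near-projecting list, which shares Fezf2, had 6 of 7 members higher in CRN and a median of -3.22 (percentile 0.01). Fam84b had 11750 reads over 4 CRN cells (7843 in CRN cell 3) and 1 read in CPN, and Crym was higher in CPN (37.6 against 10.1 CPM), though not without CPN cell 3 (log2 ratio -0.48; 3.20 without CRN cell 17). All 6 measured members of the layer 6 list were higher in CRN (median -2.39, percentile 0.80), among them Hs3st4 (39.8 against 4.07 CPM) and Tle4 (35.1 against 16.1 CPM; log2 ratio -1.13, and -0.44 without CRN cell 17), while Foxp2 had 1854 reads over 3 CRN cells (1520 in CRN cell 17) and 2 reads in 1 CPN cell, all in cells with the suffix. In cells with and without the suffix the log2 ratio was -2.28 and 0.31 for Tle4, -4.36 and -9.53 for Etv1, and 1.64 and 7.50 for Crym. Fezf2 had reads in 5 of 10 and 2 of 8 CRN cells.

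The layer 5 intratelencephalic median was -4.13 in cells with the suffix and -2.35 in cells without it. The other deep-layer lists depended on the class and on single cells: in cells without the suffix the medians were -0.74 for layer 5 extratelencephalic and near-projecting neurons and -0.77 for layer 6, within the middle 95% of random lists (percentiles 30.5 and 34.1), and the layer 6 value is what genes with almost no reads in either group give. Leaving out CRN cell 17 brought the layer 6 median to -1.15 and leaving out CPN cell 23 brought it to -5.51, and without CRN cell 18 and without CPN cell 6 the layer 5 extratelencephalic median was -2.32 and -5.31.

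Upper-layer lists stood within the middle 95% of random lists. The layer 2/3 list had 5 members higher in CPN and 8 in CRN (median -0.20, percentile 33.8; 0.35 with the suffix and -0.20 without it). Cux2, a transcription factor of upper layers, was at 66.1 CPM in CPN and 24.8 CPM in CRN and was detected in 20 of 23 and 11 of 18 cells, but its log2 ratio was 3.33 in cells with the suffix and -0.13 in cells without it. Calb1, a calcium buffer, was at 356 CPM in CPN and 229 CPM in CRN, Cdh13 at 0.590 and 128 CPM, and Agmat at 7.95 and 19.3 CPM. The Cdh13 log2 ratio of -7.76 was -3.20 without CRN cell 10, and all but 3 of its 226 CPN reads were in CPN cell 6. That of Agmat, -1.28, was 1.16 without CRN cell 4 and -2.34 without CPN cell 23. The layer 4 list as fixed at the start split evenly, 4 against 4 (median -0.42, percentile 25.4, and 0.50 without CRN cell 15). Rorb, Rspo1, Cux2 and the potassium channel gene Kcnh5 (42.4 against 6.84 CPM) were higher in CPN. Hsd11b1, Whrn, Endou and Plcxd3 were higher in CRN. Hsd11b1 had 0 CPN reads against 8866 reads over 5 CRN cells, 6213 of them in CRN cell 7. Whrn was at 9.80 CPM in CPN and 32.2 CPM in CRN. Its log2 ratio was -1.71, or -0.62 without CRN cell 7 and -3.43 without CPN cell 19. Whether each member marks layer 4 was not tested, so the even split describes this list and not layer 4 as such. The layer 4 median was 2.76 (percentile 99.99) in cells with the suffix and -0.12 in cells without it. The list of callosal projection identity had 9 members higher in CPN and 8 in CRN (median 0.27, percentile 94.8; 0.44, percentile 99.8, with cells weighted equally). Its examples were Lpl (72.1 CPM in CPN and 27.9 in CRN), Chn2 (119 and 55.8), Plxnd1 (8.69 and 43.6) and Cited2 (45.5 and 84.1). Lpl had a log2 ratio of 1.37, or 0.16 without CPN cell 23 and 2.23 without CRN cell 9, and Cited2 one of -0.89, or -0.10 without CRN cell 17. The direction turned between cells with and without the suffix for Whrn (log2 ratios 3.08 and -4.94), Lpl (1.73 and -0.55), Cited2 (-1.31 and 0.23) and Calb1 (0.93 and -0.07). The size differed for Kcnh5 (4.16 and 1.27), Plxnd1 (-0.63 and -3.47) and Agmat (-1.37 and -0.11).

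The pan-neuronal list differed little in all cells together. Of 10 pan-neuronal genes, 8 were higher in CPN (median 0.27, percentile 89.1; 0.51, percentile 97.6, in cells with the suffix), with the synaptic vesicle protein gene Snap25 at 9570 CPM in CPN and 5497 CPM in CRN and Tubb3 at 296 and 155 CPM. Nefm, a neurofilament gene, went the other way (110.5 and 304 CPM), as did Eno2 (578 and 838 CPM). The glutamatergic list had 8 of 11 members higher in CPN (median 0.67, percentile 99.97), led by the transcription factors Neurod6 (257 and 93.7 CPM) and Tbr1 (214 and 82.6 CPM), with Camk2a at 281 and 340 CPM, where the direction turned without CRN cell 8 (log2 ratio -0.27, and 0.10 without it). The log2 ratio of Neurod6 was 1.46, or 2.59 without CRN cell 1. In cells without the suffix the list median was 0.20 (percentile 75.6). The GABAergic list had 3 measured members (median 1.16, percentile 93.8; 1.40 with the suffix, -0.11 without it and -0.19 with cells weighted equally), with Maf at 48.6 CPM in CPN and 1.65 CPM in CRN and Reln at 61.3 and 27.4 CPM. Without CPN cell 23 this median, which is the value of Reln, was -0.98 and without CRN cell 3 it was 2.33. The log2 ratio of Maf, 4.88, was 5.78 without CRN cell 4. In cells with and without the suffix the ratios were 1.14 and -0.98 for Camk2a, 1.40 and -0.11 for Reln, -0.70 and -2.33 for Nefm, 2.14 and 1.18 for Neurod6, and 4.61 and 6.07 for Maf.

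Among receptors and channels, GABA receptor subunits stood apart. Of 14 members, 10 were higher in CPN and 4 in CRN (median 0.64, percentile 99.98). Gabrd was at 105 CPM in CPN and 44.0 CPM in CRN (log2 ratio 1.26, and 2.26 without CRN cell 4), whereas Gabrb1 (72.8 and 86.1 CPM) was higher in CRN, though not without CRN cell 1 (log2 ratio -0.24, and 0.13 without it). With cells weighted equally the median was 0.33 (percentile 97.0), inside the middle 95%. Glutamate receptors split 11 against 10 (median 0.00, percentile 65.4; 0.28 with the suffix and -0.39 without it), with Grm3 (114 and 31.0 CPM) and Grin2a (30.7 and 11.5 CPM) higher in CPN and Grik2 (25.8 and 55.9 CPM) and Grm5 (357 and 493 CPM) higher in CRN. Of 38 voltage-gated channel genes, 23 were higher in CPN (median 0.07, percentile 86.5), such as Cacna1g (62.3 and 16.7 CPM), and 15 in CRN, such as Kcna6 (13.4 and 53.9 CPM). Neuromodulator and peptide receptors had 10 members higher in CPN, with Npy1r (87.8 and 19.6 CPM) and Chrna4 (21.1 and 4.34 CPM) as examples, and 14 in CRN, with Sstr2 (5.41 and 22.5 CPM) and Adrb1 (38.4 and 64.1 CPM), for a median of -0.19 (percentile 49.7; 0.08 with the suffix and 0.27 without it). Neuropeptides split 4 against 3 (median 0.06, percentile 66.8; 0.91, percentile 99.2, with cells weighted equally, and -1.55 without CPN cell 16); Penk was at 188 CPM in CPN and 29.9 in CRN, and Grp at 8.98 and 17.0. The Grp log2 ratio of -0.92 was 0.25 without CRN cell 4 and -4.86 without CPN cell 16. That of Penk, 2.65, was 1.70 without CPN cell 23 and 3.41 without CRN cell 4, and that of Adrb1, -0.74, was 0.09 without CRN cell 10. Those of Sstr2 (-2.06), Kcna6 (-2.01) and Chrna4 (2.28) were -3.16 without CPN cell 9, -2.68 without CPN cell 19 and 2.97 without CRN cell 12. The voltage-gated channel median turned from 0.50 (percentile 99.9) in cells with the suffix to -0.27 (27 of 38 higher in CRN) in cells without it, and was -0.07 with cells weighted equally. The neuropeptide median turned from -0.46 with the suffix to 1.70 (percentile 99.3) without it. The direction turned between cells with and without the suffix for Adrb1 (-1.52 and 0.64), Gabrb1 (0.20 and -0.68) and Grp (-0.96, against 133 CPN and 0 CRN reads). The size differed for Gabrd (1.46 and 0.57), Grm3 (3.39 and 0.86), Grin2a (0.47 and 4.06), Cacna1g (3.40 and 1.26), Chrna4 (1.80 and 6.18), Sstr2 (-6.54 and -1.01) and Penk (2.72 and 0.31).

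**Figure D4:**
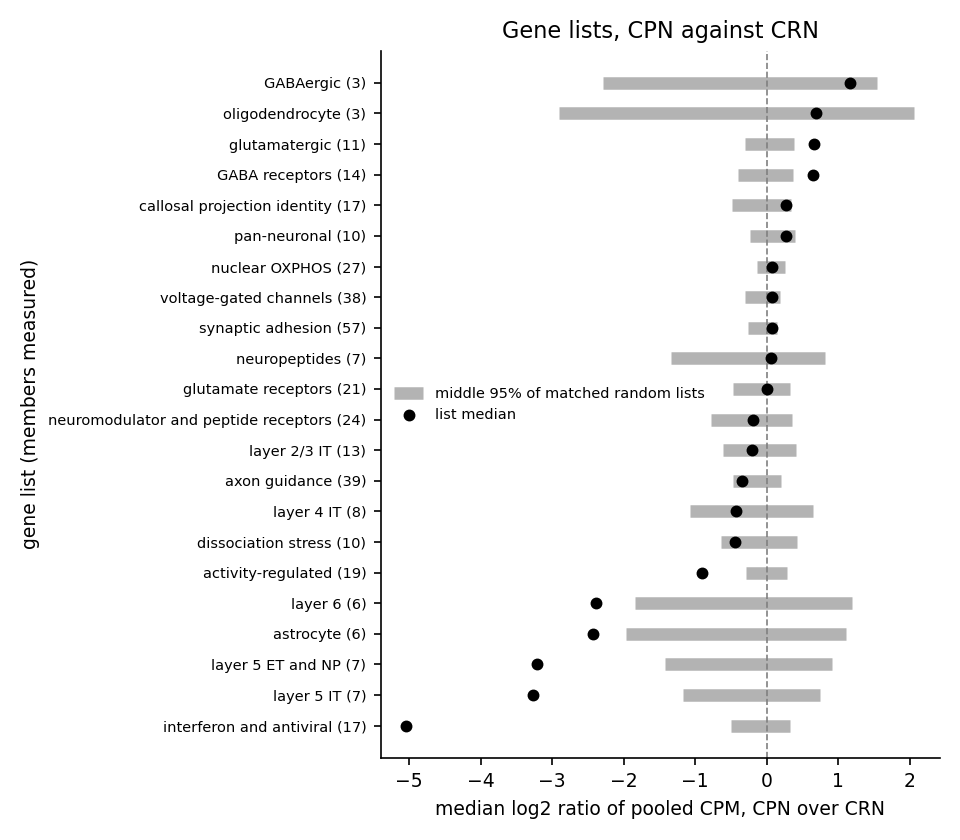
Median log2 ratio of pooled CPM, CPN over CRN (horizontal axis), for the 22 gene lists with at least 3 measured members (vertical axis, number measured in brackets); points are list medians and grey bars the middle 95% of 10000 random lists matched on expression. The interferon list lies furthest to the left at -5.04, and the GABA receptor (0.64) and glutamatergic (0.67) lists lie to the right of their bars.

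Guidance and adhesion genes showed no common direction. Of 39 axon guidance genes, 24 were higher in CRN and 15 in CPN (median -0.35, percentile 9.38), but in cells with the suffix 21 were higher in CPN (median 0.27, percentile 92.6; -0.20 without the suffix). Sema3e was at 164 CPM in CRN and 14.6 in CPN, Sema3a at 38.6 and 99.9, and Ephb1 at 9.87 and 29.0. The Sema3e log2 ratio of -3.49 rested on CRN cell 10, without which it was -0.40 (-4.30 without CPN cell 8), and that of Ephb1, 1.56, was 0.94 without CPN cell 18 and 2.17 without CRN cell 17. Synaptic adhesion genes split 31 against 26 (median 0.07, percentile 89.3), with Lrrtm2 (89.9 CPM in CPN and 34.5 in CRN) and Cdh10 (111 and 42.9) higher in CPN and the protocadherin gene Pcdh19 higher in CRN (3.80 and 43.0 CPM; log2 ratio -3.50, and -4.22 without CPN cell 1). The adhesion median turned from 0.34 (percentile 99.2; 37 of 57 higher in CPN) in cells with the suffix to -0.30 (percentile 7.70; 37 of 57 higher in CRN) in cells without it, and was -0.05 with cells weighted equally. Sema3e turned between the classes, with a log2 ratio of -4.37 in cells with the suffix and 2597 CPN against 0 CRN reads in cells without it. The ratios were 0.65 and 3.57 for Ephb1, 1.91 and 0.48 for Cdh10, and -2.82 and -5.24 for Pcdh19.

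The activity-regulated list had 14 of 19 members higher in CRN (median -0.90, below all random lists), with Fos at 548 CPM in CRN and 117 in CPN and Btg2 at 67.0 and 9.75, while Egr3 (322 and 510 CPM) and Egr2 (22.7 and 31.5 CPM) were higher in CPN. This direction rested on CRN cell 10, without which the median was 0.25, and it was -2.17 in cells with the suffix and 1.30 in cells without it. The log2 ratio of Fos, -2.23, was -0.77 without CRN cell 10. That of Btg2, -2.78, was -1.62 without CRN cell 17, and that of Egr2, 0.48, was -0.51 without CPN cell 2 and 1.31 without CRN cell 17. With cells weighted equally the list median was -0.19 (percentile 6.85). Of 10 dissociation stress genes, 8 were higher in CRN (median -0.44, percentile 9.20). Ddit3, a transcription factor of the integrated stress response, was at 245 CPM in CRN and 36.2 in CPN (log2 ratio -2.76, and -4.19 without CPN cell 23), and Atf3 had 24470 reads over 3 CRN cells (22533 in CRN cell 10) and 2 reads in CPN, all in cells with the suffix, while Hspa1b (5.87 and 7.75 CPM; log2 ratio 0.40, 1.48 without CRN cell 8 and -0.02 without CRN cell 10) and Dnajb1 (78.1 and 84.9 CPM; 0.12, and -0.18 without CPN cell 2) were slightly higher in CPN. Nuclear genes of oxidative phosphorylation split 17 in CPN against 10 in CRN (median 0.08, percentile 60.7), none by 2-fold, with Ndufb3 (218 and 124 CPM) and Cycs (824 and 541 CPM) against Atp5g1 (269 and 416 CPM) and Uqcrc2 (276 and 388 CPM). The stress median was -0.83 (percentile 2.10) in cells with the suffix and 0.08 (percentile 67.2) in cells without it. The oxidative phosphorylation median turned from -0.17 (percentile 4.31) with the suffix to 0.50 (percentile 99.8) without it. The direction turned between cells with and without the suffix for Fos (log2 ratios -3.88 and 1.02), Egr2 (-1.27 and 1.42), Dnajb1 (-0.31 and 0.96) and Uqcrc2 (-0.99 and 0.25). The size differed for Btg2 (-3.81 and -0.57) and Ddit3 (-2.52 and -3.39).

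Lists of glia and vessels had few measured members. The astrocyte list had 6 measured members, 4 of them higher in CRN (median -2.43, percentile 1.28), but the direction rested on CRN cell 4, without which the median was 0.96. It was -3.60 without CPN cell 23 and -1.84 without CRN cell 5, and within both classes of library names it stood inside the middle 95% of random lists (-1.62, percentile 7.43, and -0.41, percentile 41.5). Aldoc was at 44.8 CPM in CPN and 7.72 in CRN (log2 ratio 2.54, and 1.64 without CPN cell 22), and Slc1a2, which neurons also express, at 733 and 480 CPM (log2 ratio 1.42 in cells with the suffix and -0.05 in cells without it). The oligodendrocyte list had 3 measured members, all higher in CPN (median 0.69, percentile 86.1; 1.80 without CRN cell 8, and -1.10 with cells weighted equally), with Mbp at 90.5 and 67.6 CPM. Of the microglial list 2 members were measured, of the endothelial and mural list 1 was measured, and of the oligodendrocyte precursor and mitochondrial transcript lists 0, so that these 4 lists have no median.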

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

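All tests in this part were chosen after the results they bear on were seen.

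Reads of the reporter of the other group exceeded the 3 counts that a count of 0 allows in 8 CPN and 7 CRN cells. In CPN, mCherry was at 63.4 CPM in cell 6, 36.0 in cell 8, 32.1 in cell 7, 15.5 in cell 22, 13.4 in cell 20, 1.01 in cell 3, 0.195 in cell 19 and 0.131 in cell 23. In CRN, GFP was at 31.4 CPM in cell 15, 4.95 in cell 10, 4.53 in cell 16, 3.99 in cell 9, 3.74 in cell 18, 0.829 in cell 17 and 0.521 in cell 4. The suffix in the library name was carried by 7 of these 8 CPN cells and 7 of these 7 CRN cells, against 20 of all 41 cells.

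The first pattern is the higher level of interferon genes in CRN. Microglial RNA is argued against by the microglial genes counted here, which together reached 0.460% of the summed interferon level in CRN: P2ry12 had 0 reads and Cx3cr1 1 read there. A difference between the classes of library names as the whole cause is argued against by the weaker of the class medians, -3.59. After thinning cells to the same number of reads, which left out the shallowest cell, the median was -5.03. Thinning gives the cells equal weight, so this value argues against the weight of deep libraries as the whole cause. It cannot test other effects of depth. What stays open is whether the response goes with receiving callosal input or with the labelling of these cells: all 18 CRN cells carry mCherry and no CPN cell carries it as its main reporter, so the construct, its route and the cell class cannot be told apart in this design. Within CRN, the summed interferon level was 8312 CPM in cell 10, which had the most mCherry (5557 CPM). It was 172 CPM in cell 13, which had the least (625 CPM). The highest sum was in cell 17 (13930 CPM, with mCherry at 1933 CPM) and the lowest in cell 9 (91.8 CPM, with mCherry at 1685 CPM). Next to cell 10 in mCherry were cells 18, 6, 3, 12, 7 and 14 (4741, 3878, 3873, 3730, 3182 and 3149 CPM). Their sums were 2102, 2257, 7161, 5307, 1664 and 2865 CPM. Cells 11, 8, 4, 5, 16, 1, 15 and 2 had 2249, 2225, 2006, 1454, 1434, 1293, 1076 and 944 CPM of mCherry. Their sums were 1018, 459, 173, 2522, 148, 242, 1511 and 463 CPM. Sums thus tended to be higher in cells with more mCherry, with exceptions such as cells 5 and 17. Whether the levels of mCherry and of these genes go together over CRN cells was not tested. The animals are a further open factor, since they are not named.

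The second pattern is the higher level of layer 5 genes in CRN. The list median for layer 5 intratelencephalic neurons was -2.35 in the weaker class of library names and -3.09 after thinning. For this list, the values argue against the name classes and the weight of deep libraries as the whole cause. Other effects of depth cannot be tested by thinning. The layer 5 extratelencephalic and near-projecting median was -0.74 (percentile 30.5) in cells without the suffix, so for that list the name classes are not argued against. Chance in which cells or animals were sampled cannot be told apart from a difference between the populations: 0 of 23 CPN cells with Fezf2 allows a share of up to 14.8%, and that limit assumes independent cells. Deep-layer markers were not absent from CPN (reads of Tle4 in 17 CPN and 10 CRN cells, Hs3st4 in 8 and 9, Crym in 5 and 4), while Fezf2 (0 and 7 cells) and Fam84b (1 and 4) were seen more in CRN; a difference in the layers that the sorted groups come from stays open, as untested.

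The third pattern is CPN cell 6, which had reads of 14 of 17 interferon genes and a summed level of 1016 CPM, against a median of 242 CPM over CPN cells, beside the highest mCherry level among CPN; RNA of a CRN cell in that library is a candidate explanation. If the 63.4 CPM of mCherry came with such RNA, the CRN cell with the largest scaled sum (CRN cell 17) would bring 44.9% of the summed interferon level, or 59.0% of its excess over the CPN median (a bound of 50% on the former was dropped after the value was seen, because it ignores the level present in other CPN cells). These percentages compare sums and are not shares explained gene by gene. For Ifit1 the highest scaled CRN level was 148 CPM, against 96.0 CPM in CPN cell 6. For Rsad2, Usp18 and Irf7 it was 34.3, 7.60 and 5.40 CPM, against 0 reads in that cell. Of the 6 members above every other CPN cell, 5 exceeded what any of the 18 CRN cells would bring in proportion to mCherry (Isg15 149 against 17.0 CPM, Oasl2 115 against 64.3 CPM). No sequenced CRN cell would thus bring these 5 genes in full at that proportion, but a CRN cell outside them, with less mCherry and another profile, could bring more, so mixing cannot be told apart from a response of the cell itself. In CPN cell 22, by contrast, 13 of the 17 genes had reads, but 10 of these had 10 reads or fewer.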

How the results depend on the processing

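Removal of the deepest libraries, thinned medians, TMM and median-of-ratios factors for lists, and the pseudocounts of 0.1 and 10 for lists were chosen after seeing the data; the other alternatives were fixed before. The 8 list medians outside the middle 95% of random lists have 430 alternative values, of which 423 kept their sign, 7 reversed and 56 others moved by over 1 SD of the random lists. They include 41 settings per list that each leave out 1 cell, so many kept signs were likely beforehand. The reversals were in the activity-regulated and astrocyte lists. A kept sign does not mean that a median stayed outside the middle 95%. In cells without the suffix the glutamatergic, layer 5 extratelencephalic and near-projecting, layer 6 and astrocyte medians were inside it. Their percentiles were 75.6, 30.5, 34.1 and 41.5. For the 24 genes chosen by detection and the reporters, Rnd3 reversed among cells with the suffix (-0.15) and Aen among cells without it (0.020); equal weighting and leaving out single cells were part of the choice of the 24 and could not reverse them. Other genes with a 2-fold difference also reversed: Cux2 among cells without the suffix (-0.13), Reln without CPN cell 23 (-0.98), Crym without CPN cell 3 (-0.48) and Agmat without CRN cell 4 (1.16), and the report gives further turns between the classes. Unless stated, the cause of a shift was not tested.

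With cells weighted equally the medians were -2.57 (layer 5 intratelencephalic), 0.33 (GABA receptors) and -0.19 (activity-regulated). Differences of mean log2(CPM + 1), which by construction shrink genes seen in few cells, gave 1.19 (glutamatergic), -0.92 (layer 5 intratelencephalic), -0.85 (layer 5 extratelencephalic and near-projecting), -0.70 (layer 6), 0.38 (GABA receptors), 0.21 (activity-regulated, reversed), -2.83 (interferon) and -0.27 (astrocyte). With a pseudocount of 0.1 the values were 1.20 (glutamatergic), -1.43, -1.03 and -0.98 (the deep-layer lists in the same order), 0.25 (activity-regulated, reversed), -4.00 (interferon) and -0.24 (astrocyte). With 10 they were -0.43, -0.38 and -0.38 (deep-layer lists), 0.25 (GABA receptors), 0.10 (activity-regulated, reversed), -1.55 (interferon) and -0.14 (astrocyte).

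Cells with the suffix gave 1.14 (glutamatergic), -4.13 (layer 5 intratelencephalic), -2.17 (activity-regulated), -5.48 (interferon) and -1.62 (astrocyte). Cells without it gave 0.20, -2.35, 1.30 (reversed), -3.59 and -0.41 for the same lists, -0.74 for layer 5 extratelencephalic and near-projecting and -0.77 for layer 6; the last is the value that a gene with 0 reads in both groups takes there, so it carries no direction. Members with a mean of at least 10 CPM gave 0.88 (GABA receptors), and left too few for the astrocyte and layer 6 lists. Requiring only 1 read in each group gave -2.11 (layer 5 extratelencephalic and near-projecting) and -1.31 (layer 6). Without the deepest library of each group the medians were -5.94 (layer 6), 0.26 (GABA receptors), 0.37 (activity-regulated, reversed), -4.55 (interferon) and -4.02 (astrocyte). Thinned reads gave 0.26 (GABA receptors) and -0.31 (activity-regulated).

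Leaving out 1 cell at a time gave 0.42 to 0.99 (GABA receptors), -1.14 to 0.25 (activity-regulated, reversed without CRN cell 10), -3.60 to 0.96 (astrocyte, reversed without CRN cell 4), 0.50 to 0.96 (glutamatergic), -7.80 to -4.72 (interferon), -5.31 to -2.32 (layer 5 extratelencephalic and near-projecting) and -5.51 to -1.15 (layer 6). No cell had under 50% of the median number of detected genes, so that filter is void. TMM, median-of-ratios factors and totals without the 10 most abundant genes moved none of the 8 medians by that much. No paired analysis was possible because the numbers of the cells name single cells and pair none. Detection of genes at a few CPM is limited by depth in the shallowest cells. The gaps of the genes chosen by detection kept their direction at 10 CPM or more and in thinned reads. At 10 CPM or more, Dact2 was detected in 12 CPN and 4 CRN cells, Lrrc14 in 9 and 2, and Fxyd5 in 7 and 2. S100a6 was then detected in 20 and 3 cells and Isg15 in 1 and 12. GFP had a read in 11 CRN cells but reached 10 CPM in 1, so shares at 1 read can include traces.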

Other observations

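The lists and tests in this part were all chosen after the results were seen.

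Each list drawn up here holds genes whose values had prompted it, so results without those genes are given. Of 13 other genes in a list drawn up for nucleic acid sensing, 13 were higher in CRN (median log2 ratio -4.36). Among them was Ifih1, a sensor of double-stranded RNA (100 CPM in CRN and 4.87 in CPN). This list also held genes that are not sensors, such as the interferon receptor genes Ifnar1 and Ifnar2. Its median was -5.06 in cells with the library name suffix and -0.77 in cells without it (percentile 21.6), the latter being the value of genes with 0 reads in both groups. Whether this list and the next differ between the groups apart from the interferon pattern was not tested. Of 9 other genes of antigen presentation, 9 were higher in CRN (median -1.83), but the median was within the middle 95% of random lists with cells weighted equally (-0.90, percentile 3.5) and in cells without the suffix (-0.59, percentile 28.9), against -2.87 in cells with it. Among p53 targets, 10 of 11 others were higher in CRN (median -1.15, below percentile 2.5 of random lists in both classes of library names), with Mdm2 at 96.4 CPM in CRN and 43.5 CPM in CPN. With the prompting genes included the medians were -7.28, -2.26 and -1.21, and in cells without the suffix all 3 lists were then within the middle 95% (percentiles 18.3, 27.1 and 2.78); Sesn1, a prompting gene of the p53 list, was higher in CPN (143 and 46.9 CPM).

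A hypothesis raised by Mthfd2, Phgdh and Shmt2 is that genes of the ATF4 response and of serine synthesis are higher in CRN as a group. Of 27 such genes, 27 were higher in CRN. Without the 3 genes that raised it, 24 of 24 were higher in CRN, with a median of -1.45, below all random lists, so the direction may extend beyond them; the median nearer to 0 of the classes of library names was -1.59. Examples were Psat1 (84.7 CPM in CRN and 8.14 in CPN), Asns (355 and 157 CPM), Chac1 (71.7 and 3.57 CPM) and Atf4 itself (357 and 192 CPM). The list was drawn up after the genes of these cells had been ranked, and the labelling and the animals stay open as sources of the difference.

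Fezf2 reads in CRN were found in cells 3, 5, 6, 12, 14, 17 and 18, at 29.7, 127, 24.0, 47.0, 100, 136 and 237 CPM. These cells had reads of 15, 12, 11, 14, 16, 17 and 14 of the 17 interferon genes, in the same order. Their summed interferon levels were 7161, 2522, 2257, 5307, 2865, 13930 and 2102 CPM. CRN cells 1, 2, 4, 7, 8, 9, 10, 11, 13, 15 and 16 had no Fezf2 reads. They had reads of 4, 9, 9, 12, 7, 2, 17, 8, 6, 12 and 9 of these genes. Their summed levels were 242, 463, 173, 1664, 459, 91.8, 8312, 1018, 172, 1511 and 148 CPM. The interferon and Fezf2 patterns thus rested in part on the same cells, with CRN cell 10 as a clear exception. No test was made, since the cells were picked by a measured gene.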
